A study of Mus musculus with 2 samples.

How the data were processed

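ATAC-seq libraries were made from pooled forebrains of mouse embryos at 11.5 days of development by Nextera tagmentation, with fragments of 200 to 750 bp, per the labels. The 2 libraries are biological replicates of 1 group, and each came from 1 pool of embryos of both sexes. The authors deposited 12 peak lists on mm10: an IDR-thresholded, an IDR-ranked and a pseudoreplicated list for each replicate, and 6 lists called on both replicates together. IDR, the irreproducible discovery rate, ranks peaks by how well they repeat between replicates or between random parts of the reads. A pseudoreplicated list, in general, holds peaks found in both random parts of the reads, and a replicated list those found in both replicates. The lists were derived from the filtered alignments of the libraries, per the file headers, while the aligner, the peak caller, their settings and any shift of reads for the transposase were not given in the sources used here. Different read shifts or filters could move summits and admit or remove regions in repeated sequence.

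Each deposited list gives a score per peak in column 5, and the lowest score in each thresholded list was 540. The deposited signal value in column 7 has no stated scale, so it was used for ranks within a list and for correlation, and is otherwise printed as deposited. The deposited −log10 p in column 8 was used in an alternative and in tests of matched regions. The deposited summit offset in column 10 gives other information, the summit position in bp from the peak start. The lists hold no counts or depths, so no total per library could be given and no count model was used.

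A peak region was listed several times, once for each summit: replicate 1 had 52918 summits in 19669 regions and replicate 2 had 48403 in 18452. Each region was taken once, with its strongest summit, a choice made after the lists were seen; counting every summit was tried as an alternative. Regions on chromosomes 1 to 19, X and Y were used. The pooled list is the IDR-thresholded list of both replicates together. Gene models were the 21938 protein-coding genes of GENCODE release M21. A promoter reached 1000 bp to each side of any annotated start site, and a region was a promoter region if its summit lay in one and distal otherwise.

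The tests, 23 gene lists, 32 consensus motifs, alternatives and the rule for naming genes were fixed before the data were examined. Overlap needed 1 bp, with exact Clopper-Pearson 95% intervals, and was set against 100 seeded shuffles of regions within chromosomes. A gene was open if a region of each replicate overlapped its promoter, wherever the summit of that region lay. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. A percentile ranks the strongest region that overlaps a gene's promoter among all regions of its replicate. Distal regions found in both replicates went to the nearest protein-coding start site within 500 kb. Their mean number per gene was compared with 10000 random lists matched on decile of territory length, two-sided.

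Motifs were sought on both strands within 100 bp of the summit and compared with 2 windows per region from the same chromosome, outside all deposited peaks and matched on GC in bins of 2%. A call needed an adjusted p under 0.05 and a ratio of at least 1.25 or at most 0.8. Windows without a matched background were left out, 39 distal and 563 promoter ones. Where too few background windows matched, they could be drawn more than once, which the tests and intervals do not allow for. A background count of 0 was set at 3 matches, which makes the ratio a lower bound. No paired analysis was possible because there is 1 group.

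Genes were named by rule: from each list the 2 with the strongest promoter regions and the alphabetically first 2 with none, from each list called in the distal test the 2 with most distal regions, the 12 genes with most distal regions, and the 8 strongest regions. Motifs past both thresholds were named. BLAST+ 2.17.0 was used at an e-value of 1e-10. Regions were counted as matching the mitochondrial genome at any length and identity, nuclear segments matching it needed 100 bp, and other nuclear copies needed 100 bp and 95% identity. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

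Alternatives were the summits at or above the median signal of all summits of each list, the pseudoreplicated lists and each replicate alone. The first is called above the median signal here, and a region stayed in if its strongest summit did. Others were other overlap rules, −log10 p in place of signal, promoter windows of 500 and 2500 bp, a single start site and the pooled list. Further ones were random lists matched on promoter CpG, regions within 100 kb, no territory matching and distal beyond 5000 bp. For motifs, 50 bp windows, flanking windows and the reversed consensus were used. The flanking windows lay 1000 bp to each side of the summit, outside all deposited peaks, and were matched on neither GC nor CpG. Alternatives added after the data were seen were counting every summit, leaving out regions that match the mitochondrial genome, and a background matched on GC and CpG number.

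The procedures were tested on simulated data. An overlap of 75.0% was recovered as 75.0%. Over 50 simulated sets, 100% of changed promoter lists were called and 1.23% of unchanged ones. The changed lists were simulated with nearly all or nearly none of their genes open, and openness did not depend on CpG content. These shares therefore do not give the power for smaller differences or the rate of calls due to CpG content. Over 20 sets with 3 lists raised 4 times, 98.3% were called in the distal test and 0% of unchanged ones. Counts were simulated for each gene separately, with a mean set by its territory decile, which the test matches on. The 0% therefore does not give the rate of calls for clustered genes or for counts that depend on other features. The receptor gene lists were left out of both simulations of gene lists. With a SOX site written into 4.99% of 5250 background windows, the SOX share went from 7.05% to 11.8%, SOX had a ratio of 1.47 and 0 other motifs were called. The IDR-ranked lists were used only to check the thresholds and for peaks that the thresholded lists leave out.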

Results

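Open chromatin was mapped by ATAC-seq, in which a transposase cuts accessible DNA and adds sequencing adapters to it, in forebrain dissected from B6NCrl mouse embryos at 11.5 days of development. There was 1 group with 2 biological replicates, each a mixed-sex pool: 109 embryos in replicate 1 and 88 embryos in replicate 2. Replicate 1 had 19669 open regions covering 20.01 Mb, and replicate 2 had 18452 open regions covering 18.4 Mb of the mm10 genome. The list called on both replicates together, the pooled list, had 25691 regions with a median width of 1025 bp, which covered 1.00% of the sequenced genome. The deposited peak lists hold no read counts, so the depth of each library is unknown. With 1 group there was no contrast between conditions, and the comparisons were between the replicates, between gene groups and between kinds of sequence. Neither regions nor genes are independent replicates, so each test over them describes these 2 pools, and each interval covers counting error only.

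The pools of embryos had most of their open regions in common, and promoter regions more often than distal ones. In replicate 1, 82.6% of the regions (16252 of 19669; exact 95% interval 82.1 to 83.2%) overlapped a region of replicate 2. In replicate 2, 88.2% (16273 of 18452; 87.7 to 88.7%) overlapped a region of replicate 1. Among promoter regions, those whose strongest summit lay within 1000 bp of the start site of a protein-coding gene, 92.5% of replicate 1 and 95.2% of replicate 2 were found in the other replicate. Among distal regions, all others, the shares were 68.7% and 77.4% (two-sided Fisher's exact test in replicate 2, p = 1.6e-288). The Jaccard index of the covered bases was 0.700. After 100 shuffles of replicate 2 within chromosomes, the mean overlap was 1.49% for replicate 1 and 1.58% for replicate 2, the mean Jaccard index was 0.00388, and no shuffle came as high, which gives the smallest possible share, 0.0099.

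Regions found in 1 replicate alone were mostly weak. In the lowest signal quartile, 56.9% of replicate 1 and 67.9% of replicate 2 regions were shared, against 99.9% in the highest signal quartile in both. Of the 3417 unshared regions of replicate 1, 94.3% (93.4 to 95.02%) lay in the more lenient pseudoreplicated list of replicate 2. The same was true of 95.7% (94.7 to 96.5%) of the 2179 unshared regions of replicate 2. Across 16138 matched regions the signal values of the replicates had a Spearman correlation of 0.909 and a Pearson correlation of 0.913 on the log10 scale. For promoter regions the Spearman correlation was 0.921, and for distal regions it was 0.811. These correlations are across regions, not samples, and carry no p.

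The deposited pooled lists were nested to different degrees. Of the regions of the pooled list, 90.0% overlapped the conservative list, which had 26034 regions, and 88.9% of the conservative list overlapped the pooled list. Nearly all pooled regions, 99.7%, lay in the replicated list. That list had 61478 regions, of which 41.7% overlapped the pooled list.

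Promoters held more of the open regions than exons, introns or intergenic sequence did in the thresholded lists. The promoter share was 59.6% ± 1.61 (SD, n = 2), and it was 49.2% in the pooled list, 12.4 times the 3.96% of shuffled regions. Introns held 17.5% ± 1.03 (SD, n = 2) of the regions and 22.9% of the pooled list, against 40.9% of its shuffles. Intergenic sequence held 19.8% ± 0.584 (SD, n = 2) and 24.5% of the pooled list, against 51.2%. Exons held 3.04% ± 0.00743 (SD, n = 2) and 3.44% of the pooled list, against 3.98%. Each of the 100 shuffles had a lower promoter share than the pooled list, and the highest was 4.31%. Promoter regions also had higher signal than distal ones, with a median of 8.66 against 6.19 in replicate 1 and 8.91 against 6.36 in replicate 2. In the pseudoreplicated lists, which admit weaker regions, the promoter share was 33.5% over the replicates and 27.8% in the pooled list.

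**Figure D1:**
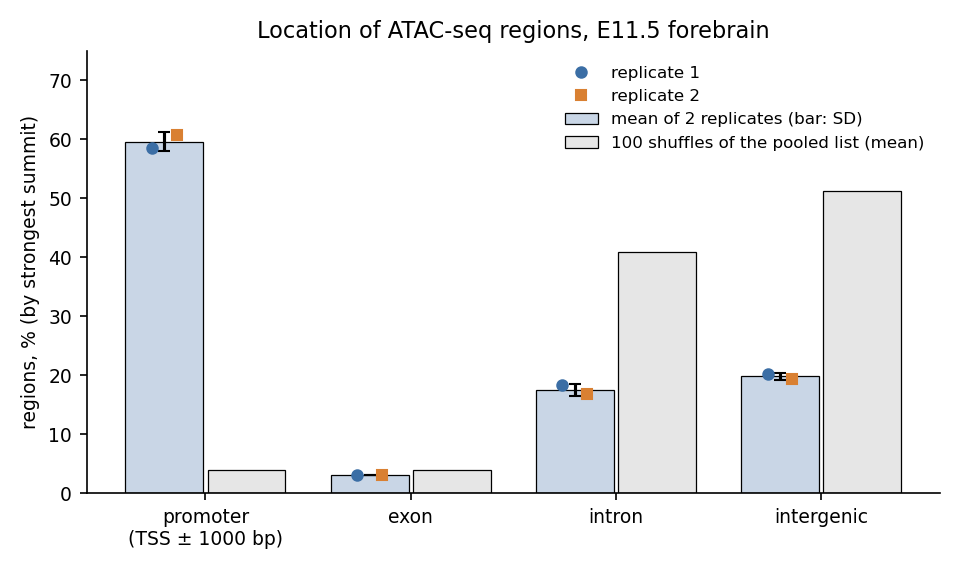
Share of open regions (percent, vertical axis) in promoters, exons, introns and intergenic sequence. Bars give the mean of the replicates with its SD, with replicate 1 (circles) and replicate 2 (squares), beside the mean of 100 shuffles of the pooled list. Promoters held 58.4% of replicate 1 and 60.7% of replicate 2 regions, against 3.96% of shuffled regions. The pooled list, with 49.2% in promoters, is not drawn.

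The sex chromosomes had fewer open regions for their length than the autosomes. Autosomes carried 7.94 regions per Mb in replicate 1 and 7.45 in replicate 2, with the highest density on the gene-rich chromosome 11, at 10.4 and 9.84 regions per Mb. Chromosome X had 0.486 ± 0.00642 (SD, n = 2) of the autosomal density, and its density of protein-coding genes was 0.668 of the autosomal one. Chromosome Y held 13 regions in each replicate, 0.0192 ± 0.000875 (SD, n = 2) of the autosomal density, with a gene density of 0.239 of the autosomal one. The Y ratio was 0.0117 when every summit was counted in place of regions. None of these ratios was adjusted for the number of X and Y copies in the mixed-sex pools or for repeated sequence.

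Promoters of neural progenitor and cell cycle genes were open throughout, while promoters of Hox genes and of microglia, liver, muscle and surface epithelium genes were almost all without a region. For genes, a promoter region was any region that overlapped the promoter, wherever its summit lay. Of 21938 protein-coding genes, 11332 (51.7%) had a promoter region in both replicates, 12007 in replicate 1 and 11728 in replicate 2. All 20 neural progenitor genes had one in both replicates (two-sided Fisher's exact test against all other genes, adjusted p = 6.6e-06 over 23 lists). They included Id4, an inhibitor of basic helix-loop-helix factors, and Hey1, a Notch target, with promoter signals at the 81.8th and 61.9th percentile of regions (mean of the replicates). All 20 cell cycle genes had one as well (exact adjusted p = 6.6e-06), among them Ccna2, which encodes cyclin A2, at the 96.0th percentile and Pcna, the DNA polymerase clamp, at the 92.6th. Of 18 housekeeping genes, 16 did (exact adjusted p = 0.00276), led by Atp5b and Sdha, both of mitochondrial energy metabolism, at the 91.2nd and 90.4th percentile.

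Early neuron genes had promoter regions in 16 of 21 cases in both replicates, against 51.6% of other genes (exact adjusted p = 0.0464). Map2, a neuronal microtubule protein, lay at the 84.5th percentile and Elavl4, a neuronal RNA-binding protein, at the 74.3rd, while Ina and Neurod4 had no promoter region in either replicate. That call was lost without replicate 2 (exact adjusted p = 0.0731), above the median signal (0.910) and with a promoter window of 500 bp (0.115). It was lost too with a single start site per gene (exact adjusted p = 0.179) and against lists matched on promoter CpG content (permutation adjusted p = 0.104).

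The forebrain transcription factor lists did not pass the test at promoters. Telencephalon and anterior forebrain patterning factors had a region in both replicates in 15 of 20 cases (exact adjusted p = 0.0667), with Tcf4 at the 79.2nd percentile and Foxg1, a regulator of telencephalon growth, at the 53.8th. Hesx1 and Six6 had none. With replicate 2 alone the adjusted p of this list was 0.035, with replicate 1 alone it was 0.0405, in the pooled list it was 0.00755 and in the pseudoreplicated lists it was 0.00317. It did not pass above the median signal, with a single start site or with windows of 500 or 2500 bp. Dorsal telencephalon (pallium) factors had one in 15 of 21 cases (exact adjusted p = 0.110; 0.0188 in the pooled list and 0.00986 in the pseudoreplicated lists). Gli3, a transcription factor of the Hedgehog pathway, lay at the 71.3rd percentile and Dmrta2 at the 63.2nd, while Eomes, a marker of intermediate progenitors, and Neurod6, a marker of young excitatory neurons, had none. Ventral telencephalon (subpallium) factors had one in 12 of 20 cases (exact adjusted p = 0.556; 0.0149 in the pseudoreplicated lists), with Ebf1 at the 81.7th percentile, Isl1 at the 75.2nd and none at Gad1 and Lhx6. Diencephalon, hypothalamus and eye field factors also had one in 12 of 20 cases (exact adjusted p = 0.556), with Pitx2 at the 87.6th percentile, Sim1 at the 70.5th and none at Foxb1 and Lhx5. Forebrain signalling genes had one in 11 of 20 cases (exact adjusted p = 0.863; 0.048 in the pseudoreplicated lists). Gli3 and the WNT antagonist gene Sfrp1, at the 69.7th percentile, were their strongest, and Fgf8 and Fgf17, of the anterior signalling centre, had none. Against lists matched on promoter CpG content, telencephalon (75% against 72.6%) and pallium factors (71.4% against 71.3%) did not differ (permutation adjusted p = 1). Subpallium (60% against 78.7%, permutation adjusted p = 0.0908), diencephalon (60% against 81.6%, 0.052) and signalling genes (55% against 77.03%, 0.052) were lower without passing the test.

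Among genes that pattern more posterior parts of the nervous system, Hox genes were open less often than other genes. Of the 39 Hox genes, which specify position in the hindbrain, spinal cord and trunk, Hoxc6 (chromosome 15, 102998257 to 103011881) alone had a promoter region in both replicates (2.56%, against 51.7% of other genes, exact adjusted p = 2.0e-10). Its signal lay at the 56.9th percentile in replicate 1 and the 24.6th in replicate 2, and Hoxa1 and Hoxa10 were among the 37 with none in either replicate. Midbrain and hindbrain factors had a promoter region in 6 of 18 cases (33.3%, exact adjusted p = 0.200). Pax5 and Gata3 lay at the 85.9th and 77.7th percentile, while Barhl1 and En1, a factor of the midbrain-hindbrain boundary, had none. Against random lists matched on promoter CpG content, of which 80.2% of genes had a region, this list was lower (permutation p = 0.0002, the smallest possible, adjusted to 0.00092), as it was with a single start site per gene (exact adjusted p = 0.0135). In the pseudoreplicated lists 66.7% of it was open (1.07 times other genes, exact adjusted p = 0.810), and it was not called in the other alternatives. Hox genes stayed lower in all of them, at 0.330 times other genes in the pseudoreplicated lists and 0.131 times in the pooled list.

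Most lists of markers of cells that arise later or lie outside the neural lineage had few promoter regions. Astrocyte and oligodendrocyte genes had one in 3 of 20 cases (exact adjusted p = 0.00236), with Pdgfra at the 15.7th and Gja1 at the 13.0th percentile and none at Agt and Aldh1l1. Synaptic and mature neuron genes had one in 10 of 20 cases (exact adjusted p = 1), with Syt1, the calcium sensor of synaptic vesicles, at the 96.2nd percentile, Syn1 at the 87.5th and none at Cck and Grin1. No promoter region was found in both replicates for the 18 microglia and macrophage genes (Aif1 and C1qa among them), the 18 hepatocyte genes (Afp, Ahsg) and the 18 heart and skeletal muscle genes (Acta1, Actc1), each with exact adjusted p = 6.6e-06, nor for the 16 surface epithelium genes (Cdh1, Cldn4; exact adjusted p = 2.3e-05). Erythroid genes had 1 of 18, the regulator Klf1 at the 53.1st percentile, and none at Alas2 and Ank1 (exact adjusted p = 0.000112). Pluripotency and germ cell genes had 3 of 16 (exact adjusted p = 0.0187), with Dazl at the 66.1st percentile, Esrrb at the 36.2nd and none at Ddx4 and Dppa2. Mesenchyme, pericyte and meningeal genes had 7 of 18 (exact adjusted p = 0.421), with Snai2 at the 71.7th percentile, Kcnj8 at the 59.9th and none at Acta2 and Alx4. In the more lenient pseudoreplicated lists the open share in both replicates was 35% for astrocyte and oligodendrocyte, 33.3% for erythroid, 18.8% for surface epithelium and for pluripotency, 16.7% for muscle, 11.1% for microglia and 5.56% for hepatocyte genes, and all 7 lists stayed lower. In the pooled list the ratio to other genes was 0.285 for muscle, 0.190 for erythroid and hepatocyte and 0.107 for surface epithelium genes. With replicate 1 alone it was 0.203 for erythroid and 0.101 for hepatocyte and for muscle genes.

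Endothelial genes had a promoter region in 5 of 18 cases in both replicates (exact adjusted p = 0.0823), with Ets1 at the 93.9th percentile and Erg at the 64.3rd, and none at Cdh5 and Cldn5. They were called lower with either replicate alone (exact adjusted p = 0.0483 without replicate 1 and 0.0469 without replicate 2), above the median signal (0.0124), with a window of 500 bp (0.0279) and with a single start site (0.00283). They did not pass in the pooled list, in the pseudoreplicated lists, with a window of 2500 bp or against lists matched on CpG content (27.8% against 45.9%, permutation adjusted p = 0.135). Olfactory receptor genes had 2 of 1093 promoters with a region, Olfr658 and Olfr94, and vomeronasal receptor genes had 1 of 327, Vmn1r4 (exact adjusted p = 1.8e-101 for the latter). The olfactory p was below the smallest number the software holds. Olfr1, Olfr10, Vmn1r1 and Vmn1r10 were among the closed ones.

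Part of these differences went with CpG content, taken at the most upstream annotated start site of each gene. A region at any start site made a gene open, and the number of start sites was not matched. In the lowest decile of CpG observed/expected 2.37% of genes were open, and in the highest 93.1%. Against 10000 random lists matched on that decile, 8 lists were called in place of 14. Neural progenitor genes stayed higher (100% against 78.4%, permutation adjusted p = 0.0069). Hox genes (2.56% against 72.4%), surface epithelium genes (0% against 50.7%), olfactory receptors (0.183% against 5.18%) and vomeronasal receptors (0.306% against 4.98%) stayed lower, each at the smallest possible p of 0.0002, adjusted to 0.00092. Muscle genes (0% against 28.6%) and pluripotency genes (18.8% against 53.0%) stayed lower at 0.0046. The call was lost for cell cycle genes (100% against 80.6%), erythroid genes (5.56% against 23.4%) and astrocyte and oligodendrocyte genes (15% against 35.1%), each with a permutation adjusted p of 0.052. It was also lost for microglia genes (0% against 18.1%, 0.0667), hepatocyte genes (0% against 17.2%, 0.0757) and housekeeping genes (88.9% against 72.8%, 0.143).

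**Figure D2:**
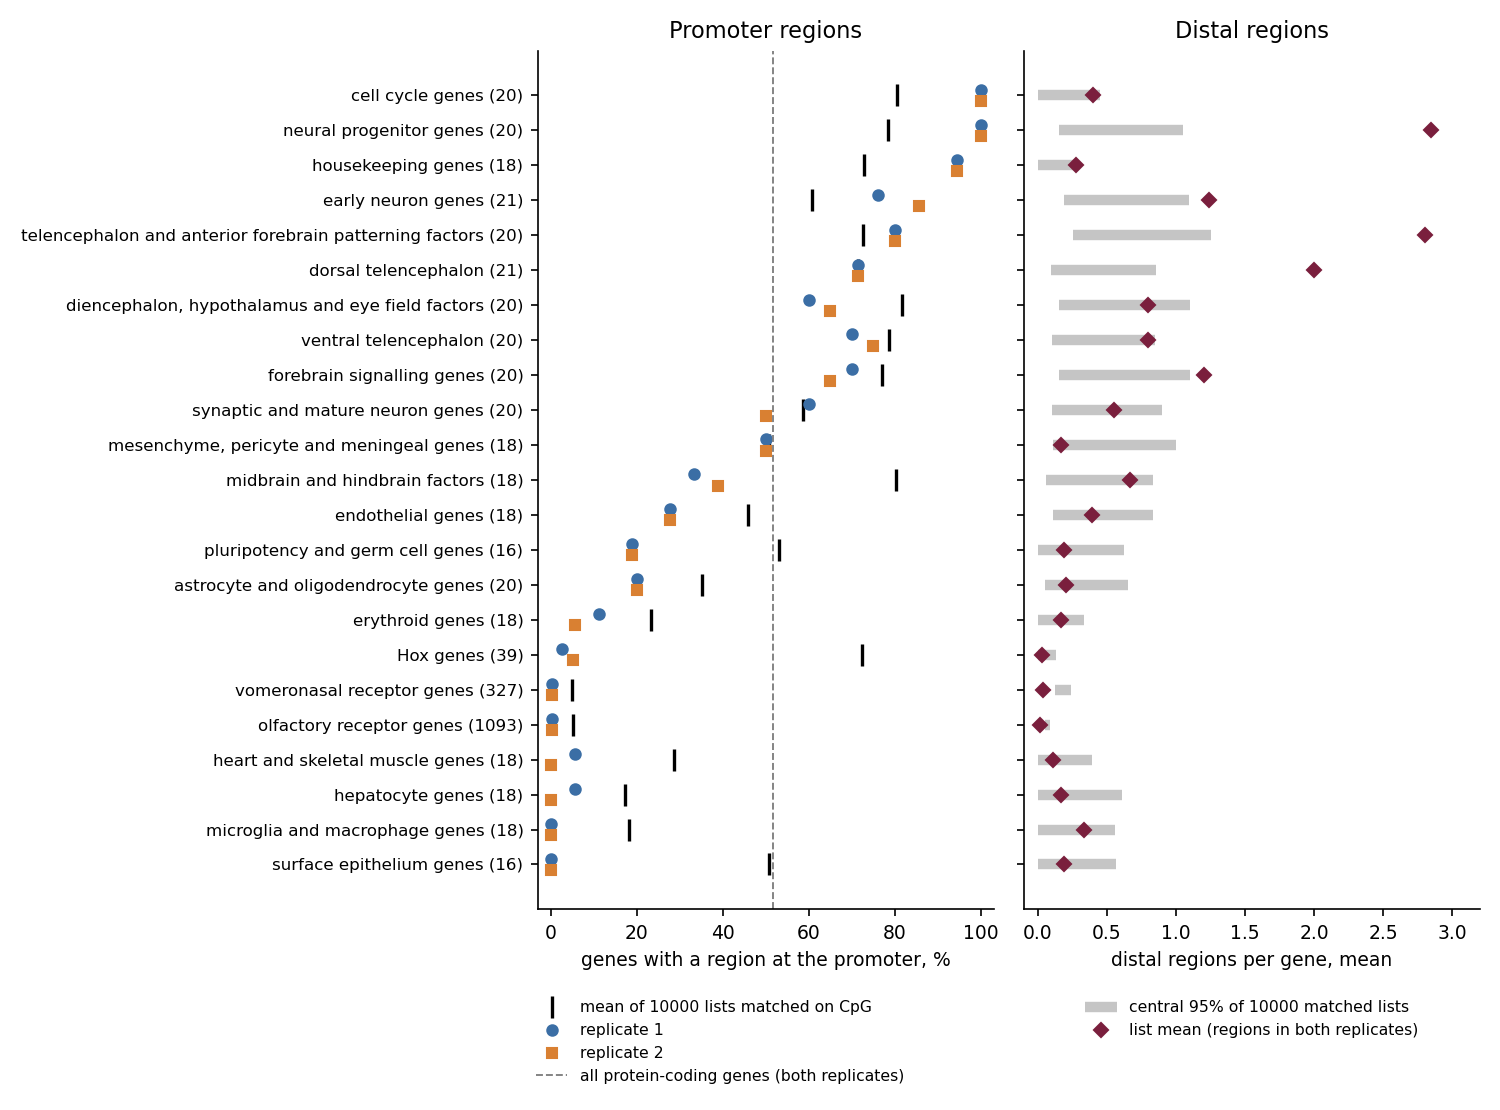
Left, percent of the genes of each list (number of genes in parentheses) with a promoter region in replicate 1 (circles) and replicate 2 (squares). Black ticks give the mean of 10000 lists matched on promoter CpG, and the dashed line the share of all protein-coding genes. Ticks and line count genes open in both replicates, as the tests did, a stricter measure than the symbols show. Right, mean number of distal regions per gene (diamonds) against the central 95% of 10000 lists matched on territory length (grey bars), where neural progenitor genes (2.85), telencephalon patterning factors (2.80) and pallium factors (2.00) lie furthest above the bars; early neuron (1.24) and signalling genes (1.20) lie above theirs too, but did not pass after adjustment.

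Distal open regions were concentrated around genes of telencephalon patterning, the pallium and neural progenitors. Of 16118 pooled regions found in both replicates, 5534 were distal, and 5331 of these lay within 500 kb of a protein-coding start site and went to 3363 nearest genes. Neural progenitor genes had 2.85 distal regions per gene, 5.39 times the 0.529 of random lists matched on territory length, the stretch of genome nearest to a gene. Telencephalon and anterior forebrain patterning factors had 2.80 against 0.659 (4.25 times), and pallium factors had 2.00 against 0.426 (4.69 times). All 3 lists were higher with each replicate alone too, and each had a two-sided permutation p of 0.0002, the smallest possible, and an adjusted p of 0.00092. Olfactory receptor genes (0.0174 against 0.0680) and vomeronasal receptor genes (0.0367 against 0.176) were lower at the same adjusted p. The size of the difference depended on the setting: neural progenitor genes were 3.55 times the random lists in the pseudoreplicated lists, and without matching on territory length they were 11.7 times, telencephalon factors 11.6 times, pallium factors 8.16 times and olfactory receptor genes 0.0718 times.

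Within these lists the regions were unevenly spread. Sox9, a transcription factor of neural stem cells and glia, had 13 distal regions and the stem cell factor Sox2 had 7. The nuclear receptors Nr2f1 and Nr2f2, which pattern the cortex along its axes, had 9 each, although the Nr2f1 promoter lay at the 1.91st percentile. Gli3 and Lef1, a WNT effector, had 5 each. Of the receptor genes, Olfr1423 had 4, Olfr161 and Vmn1r223 had 2 each and Vmn1r2 had 1.

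The other 18 lists did not pass the test. Early neuron genes had 1.24 distal regions per gene (2.22 times, permutation adjusted p = 0.0774), signalling genes 1.20 (2.19 times, 0.0841) and subpallium factors 0.8 (1.98 times, 0.252). Ratios were 1.47 for diencephalon factors (permutation adjusted p = 0.565), 1.74 for midbrain and hindbrain factors (0.384), 0.547 for Hox genes (1), 1.27 for synaptic genes (0.893) and 2.26 for cell cycle genes (0.320). They were 2.92 for housekeeping genes (permutation adjusted p = 0.285), 1.62 for microglia genes (0.690), 1.48 for erythroid genes (0.920) and 0.347 for mesenchyme genes (0.328). For the endothelial (0.998), surface epithelium (0.936), muscle (0.826), hepatocyte (0.756), pluripotency (0.743) and astrocyte and oligodendrocyte (0.676) lists, the ratios had adjusted p of 1. With replicate 2 alone, 8 lists were called in place of 5, adding subpallium factors (2.92 times, permutation adjusted p = 0.00537), early neuron genes (2.40 times, 0.0171) and signalling genes (2.22 times, 0.0385). With replicate 1 alone, signalling genes were added (2.40 times, 0.0146). In the pseudoreplicated lists subpallium factors (2.58 times, permutation adjusted p = 0.0023) and signalling genes (2.10 times, 0.0112) were called, and within 100 kb early neuron genes (2.31 times, 0.0263), signalling genes (2.54 times, 0.0092) and, lower, Hox genes (0.406 times, 0.0408). Without matching on territory length 10 lists were called, adding early neuron (5.10 times), signalling (5.01), diencephalon (3.39), subpallium (3.30) and Hox genes (0.107).

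Over all protein-coding genes, the largest numbers of distal regions in the main count lay near Mef2c, a transcription factor of neurons and muscle, with 13 (chromosome 13, 83504034 to 83667080), and near Sox9, also with 13 (chromosome 11, 112782224 to 112787760). Macrod2 had 12, Celf4, a neuronal RNA-binding protein gene, had 10, and Gse1, Nr2f1, Nr2f2, Rapgef5, Tenm4 and Tmem161b had 9 each. Btg1 and Cxxc4 had 8 each, as did Myo3a and Nrxn3, which the rule for naming genes left out on alphabetical order. Without regions that match the mitochondrial genome Myo3a had 5, and the other 13 genes kept their numbers. Among the 20 genes with most distal regions, the order depended on the list: in the pseudoreplicated lists Rapgef5 (30), Celf4 and Gse1 (28 each) and Nrxn3 (26) came before Mef2c (25), and Tenm4 (23) before Sox9 (22), and with every summit counted Macrod2 (32), Tmem161b (30) and Gse1 (29) came before both (27 each). Above the median signal Sox9 had 13 and Mef2c 7. The Sox9 regions lay 4 upstream and 9 downstream of the start site, at distances of 19.4 to 383 kb, and the strongest had a signal of 13.7.

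**Figure D3:**
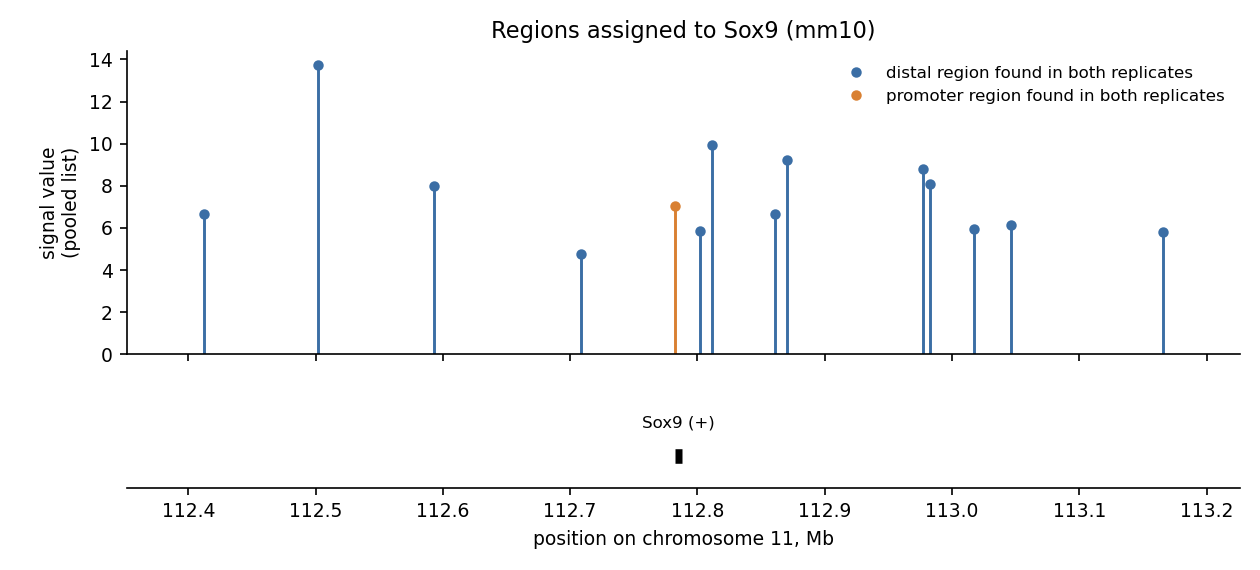
Open regions around Sox9 on chromosome 11 (mm10; horizontal axis, position), found in both replicates and nearest to its start site, with their signal value in the pooled list (vertical axis). The 13 distal regions lie between 112412065 and 113165886, and the highest has a signal of 13.7.

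Sites of CTCF, SOX, LHX/DLX, POU and proneural factors were among those more frequent in distal regions than in the background. Within 100 bp of the summit of 13023 pooled distal regions, the CTCF consensus was found in 5.87%, 61.1 times (95% interval 41.1 to 91.0) its share in windows of matched GC content outside all peaks. CTCF anchors chromatin loops. The motif tests did not require a pooled region to be found in both replicates. Of distal regions with a CTCF match 25.4% were, against 43.4% of those without. The SOX consensus was found in 14.6% of distal regions, against 6.46% of background windows (2.25 times, 2.12 to 2.40). LHX/DLX homeodomain sites were 5.75 times (4.95 to 6.68) and POU octamer sites 5.26 times (4.60 to 6.01) as frequent as in the background. Proneural E-boxes were 2.98 times (NEUROG/NEUROD, 2.54 to 3.50) and 2.60 times (ASCL1, 2.23 to 3.02) as frequent. The GATA consensus, of erythroid and endothelial regulators among others, was rarer than in the background (0.607 times, 0.4998 to 0.738, two-sided Fisher's exact test, adjusted p = 5.3e-07). Each of these motifs was called in the same direction in both replicates.

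Of 32 consensus motifs, 18 were higher and 1 lower in distal regions. The remaining calls were RFX (26 times), NFI (24.0 times, from 12 matches against 1), PAX6 (10.0 times, from 5 matches against 1), NRF1 (7.67), YY1 (5.00, from 10 matches against 4), CREB/ATF (4.04), SP/KLF (2.94), CEBP (2.62, from 17 matches against 13), ETS (2.47), NFY (2.47), LEF/TCF (1.64) and TEAD (1.43). OTX, at 1.20 times, did not reach the ratio threshold, which it passed without replicate 1 (1.37), and NKX2 (1.22), GLI (1.44), MEIS/TALE (0.971) and EBF (0.826) were not called either. PAX6 was called in neither replicate alone, YY1 and CEBP were not called without replicate 1, YY1 was not called above the median signal either, GATA was not called in the pseudoreplicated list (0.83) and LEF/TCF was not with every summit counted (1.16). In the pseudoreplicated list the ratios were also lower for NFI (8.8), PAX6 (4.5), POU (3.496), YY1 (2.67), CREB/ATF (2.65), NFY (1.51) and ETS (1.34), and REST (18 times), GLI (1.48) and NKX2 (1.30) were called higher and HNF4 (0.755) and PU.1 (0.686) lower. Above the median signal, RFX was 45.3 times, NRF1 14.7 times and NFI 4 times the background, and NKX2 was called (1.296). With 50 bp on each side in place of 100 bp, RFX was 118 times, LHX/DLX 10.4 times, ETS 3.75 times and NRF1 3.33 times the background, and NFI (3 times), YY1 (5 times), PAX6 (0.667) and CEBP (1.71) were not called. Against windows matched on CpG number as well as GC, YY1 (1.67), PAX6 (5 times) and CEBP (1.42) were not called, and NRF1 was 4.18 times, ETS 1.59 times, CREB/ATF 2.65 times, RFX 52 times and NFI 12 times the background. With the reversed consensus as background ETS turned lower (0.549), and CREB/ATF (0.944), CEBP (0.586) and PAX6 (1.67) were not called. The ratios were then 255 for CTCF, 84.4 for POU, 194 for ASCL1, 17.4 for NEUROG/NEUROD, 10 for YY1 and 6.36 for NFY. They were 4 for NFI, 3.68 for TEAD, 2.905 for LEF/TCF, 2.58 for LHX/DLX and 0.396 for GATA, while RUNX was called (2.12). Reversal puts fixed CG pairs into the CTCF, POU, ASCL1, RFX, NFI and REST consensus and adds further ones to YY1 and NRF1. It removes the CG pair of ETS and of CREB/ATF. Reversal also alters where a CG pair can occur in other motifs, among them MEIS/TALE, NEUROG/NEUROD, TEAD and GATA. For these motifs the reversed consensus therefore cannot separate a preference for the site from CpG content, here or in promoter regions. The flanking windows were not matched on GC or CpG, so ratios against them cannot be separated from base composition. With windows flanking the summit CEBP was not called (1.19), LHX/DLX (2.72), POU (2.93) and NFI (10.5) were closer to the background, and ASCL1 (6.21), NEUROG/NEUROD (4.61), SP/KLF (7.22), NFY (3.89), CREB/ATF (6.35) and RFX (68) were further from it, as was GATA (0.375), while GLI was called (2.95). With every summit counted, CTCF was 38.4 times, POU 3.295 times, YY1 2.25 times, PAX6 4.4 times, NFY 1.47 times and NFI 2.27 times the background, and REST (3.33) and GLI (1.36) were called. A single replicate moved several ratios by over 1.5 times: without replicate 1, CTCF was 102 times, RFX 110 times, NFI 7 times and NRF1 36 times the background, and without replicate 2, RFX was 60 times, NFI 8 times, CREB/ATF 6.33 times, YY1 9.33 times and CEBP 15 times.

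Of the motifs called higher in promoter regions, SP/KLF, NFY and ETS sites were found in the largest shares. In 12066 promoter regions, SP/KLF sites were found in 19.3% (3.91 times the background), NFY sites in 9.17% (20.9 times) and ETS sites in 7.003% (29.1 times). CREB/ATF sites were found in 3.17% (50.9 times), YY1 sites in 1.91% (42.0 times) and NRF1 sites in 1.57% (127 times, from 190 matches against 3). SOX (1.02 times), NEUROG/NEUROD (0.905) and ASCL1 (0.913) did not pass the test there, but these ratios depended on the setting. ASCL1 was called lower without replicate 2 (0.775) and higher with flanking windows (4.27) and with the reversed consensus (12.6). NEUROG/NEUROD was called higher with the reversed consensus (3.65) and against windows matched on CpG number (1.72), and SOX lower with flanking windows (0.707) and higher with the reversed consensus (1.29). Of the 32 motifs, 15 were higher and 2 lower. The others included RFX (46.0 times, from 23 matches against 1) and CEBP (24.5, from 49 matches against 4). Further ones were CTCF (18.3), POU (6.50), PU.1 (3.44), MEF2 (2.74) and LHX/DLX (1.76). REST was at least 8.67 times and NFI, from 4 matches, at least 2.67 times as frequent, since the background had no match and was set at 3 matches. MEIS/TALE (0.354) and EBF (0.579) were lower.

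Several promoter ratios depended on the background and on the regions used. Windows flanking the summit were not matched on GC or CpG, so ratios against them cannot be separated from base composition. Against windows matched on CpG number as well as GC, NRF1 was 18.7 times, YY1 11.9 times, CREB/ATF 7.79 times and NFY 7.68 times as frequent, and MEF2 (1.20) and NFI were not called. NFI was also called in neither replicate alone, nor in the pseudoreplicated list, with 50 bp windows, with flanking windows or with the reversed consensus. Against windows flanking the summit, NRF1 rose to 322 times, YY1 to 128 times and SP/KLF to 25.05 times, CREB/ATF fell to 29.8 times, RFX to 12.3 times and CEBP to 5.75 times, LHX/DLX (0.205) and MEF2 (0.109) turned lower, and POU (1.02), PU.1 (1.16), MEIS/TALE (0.828) and EBF (1.08) were not called, and RUNX (0.436), AP-1 (0.509), LEF/TCF (0.397), OTX (0.2045) and GATA (0.198) were called lower, while with the reversed consensus MEIS/TALE turned higher (2.61). With every summit counted most ratios were lower: NRF1 was 37.2 times, YY1 19.9 times, CREB/ATF 13.1 times, RFX 12 times, ETS 10.2 times, CTCF 7.69 times, NFY 5.93 times, CEBP 5.66 times, POU 2.42 times, PU.1 1.98 times and MEF2 1.49 times the background, and EBF was not called (0.946). In the pseudoreplicated list NRF1 was 49 times, CREB/ATF 26.6 times, RFX 18.7 times, ETS 18.1 times and PU.1 1.95 times as frequent, while CTCF was 28 times. With 50 bp windows LHX/DLX was not called (1.86), OTX was called lower (0.413), and NRF1 was 35.7 times, RFX 10.7 times, CEBP 14.5 times, ETS 47.4 times, POU 11.5 times and MEIS/TALE 0.683 times the background. Above the median signal NRF1 was 40.7 times. With the reversed consensus EBF was not called (1.10), and ETS was 10.6 times, CREB/ATF 7.94 times, RFX 7.67 times and CEBP 2.38 times as frequent, while NRF1 was 200 times, YY1 239 times, CTCF 58 times and POU 17.9 times, TEAD was called higher (2.30) and LEF/TCF lower (0.640). Without replicate 1, CTCF was 7.37 times and POU 9.89 times the background, without replicate 2, NRF1 was 72.8 times, CEBP 98 times and PU.1 1.93 times, and REST was 4 times or more with either alone.

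**Figure D4:**
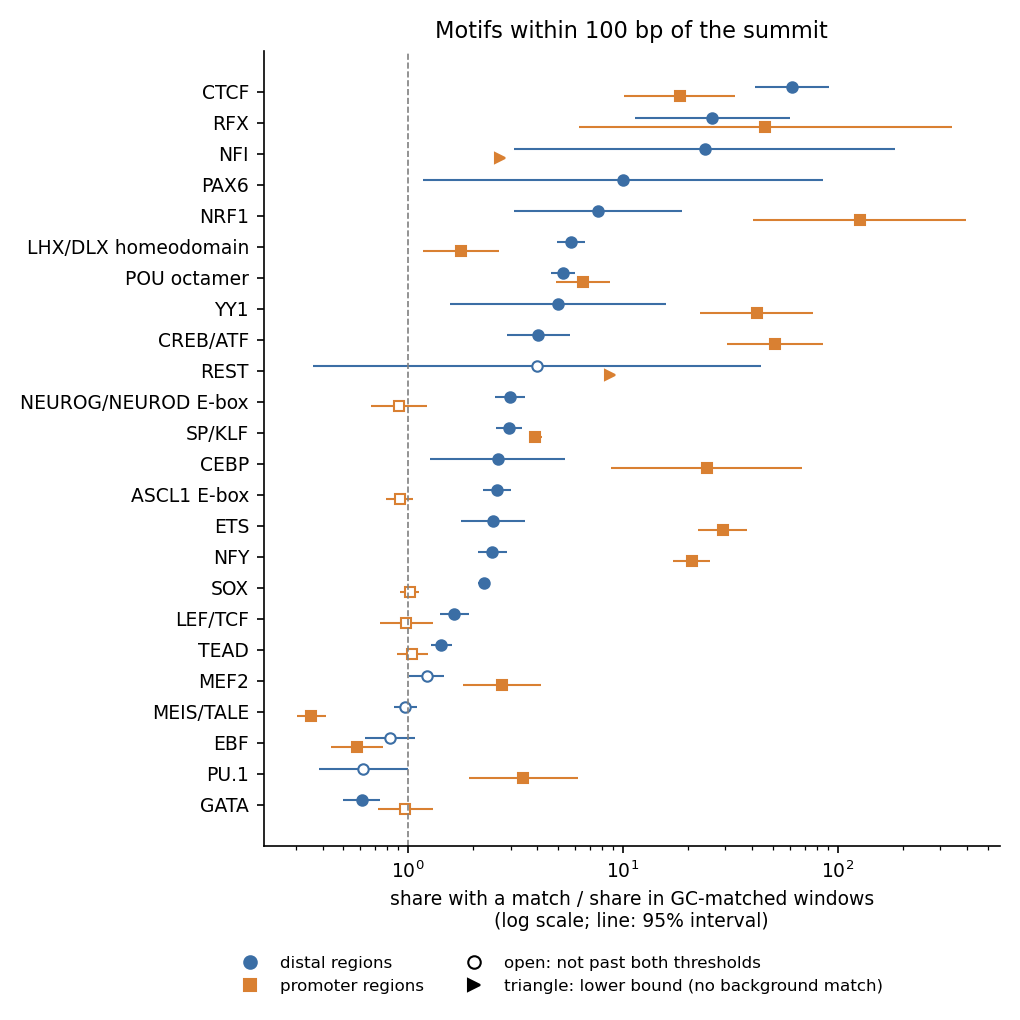
Ratio of the share of regions with a motif match to its share in windows of matched GC content (log scale), for distal regions (circles) and promoter regions (squares), with 95% intervals as lines. Open symbols did not pass both thresholds, and triangles are lower bounds. In this setting CTCF stands at 61.1 in distal regions and NRF1 at 127 in promoter regions.

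The 8 strongest regions lay outside the promoters of protein-coding genes, and 7 of them matched other sequence in the mouse genome. The highest signal, 56.3, was on chromosome X at 143482934 to 143483180, in intergenic sequence 35532 bp from the start site of Pak3. It was followed by chromosome 2, 69355469 to 69355735 (52.9, nearest gene Abcb11), chromosome 2, 3964420 to 3964690 (45.2, Frmd4a), chromosome 5, 60042765 to 60043140 (39.7, G6pd2), and chromosome 10, 96077546 to 96077951 (39.0, Gm5426, in an intron of AC115970.1). Next came chromosome 12, 97061368 to 97061856 (29.4, Galc), chromosome 4, 80002694 to 80003058 (28.3, Tyrp1, in an exon of Gm11407), and chromosome 16, 17222196 to 17222584 (27.0, Hic2). Of these 8 regions, 5 matched the mitochondrial genome, at 95.04 to 100% identity over 129 to 365 bp. The region near Pak3 had 2 and the region near Hic2 had 3 other nuclear copies, and the region near Frmd4a had neither kind of match. In the replicates' own lists the deposited signals, of unstated scale, were 54.0 and 55.0 for the first and 25.6 and 25.5 for the eighth.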

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

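The test of mitochondrial matches among the 20 strongest regions and the count of rows left out on the assembled chromosomes were chosen only after the result was seen. The others were chosen before.

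The ranked lists hold peaks on unplaced scaffolds, sequence not assigned to a chromosome, which the thresholded lists leave out. Counts here are of list rows, of which a region has 1 for each summit. In replicate 1, 70 such rows reached the lowest score of the thresholded list, 540, and in replicate 2, 82 did. They lay on 14 scaffolds in each replicate, with 24 and 21 of them on the commonest scaffold. The thresholded lists also left out rows at or above that score on chromosomes 1 to 19, X and Y. There were 167 in replicate 1 and 160 in replicate 2, of which 115 and 120 had the highest score, 1000. Why they were left out was not tested.

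The strongest regions of the pooled list matched sequence found elsewhere in the genome. Of all 25691 regions, 17 matched the mitochondrial genome (79.02 to 100% identity over 64 bp or more), and 6 of these were among the 20 strongest (two-sided Fisher's exact test, p = 1.2e-15). Of the nuclear segments with at least 95% identity to the mitochondrial genome, 87.5% (7 of 8) lay in a region. This compares with 3.26% of the 92 segments below 85% identity (exact p = 5.8e-08). The segments with at least 95% identity include those in the strong regions counted above, so this p partly restates their mitochondrial match. Reads of mitochondrial DNA placed on nuclear copies are a candidate source. Of the 20 strongest regions without such a match, 60% had another nuclear copy, against 5.33% of 300 random regions (exact p = 1.3e-09), so reads shared between nuclear copies are another. Of the 20 strongest regions, 4 had neither match and remain open: the one near Frmd4a and the promoters of 6720489N17Rik, Cfdp1 and Wdr17, these 3 named after their values were seen. No biological explanation was tested.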

How the results depend on the processing

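Values for every summit counted, for regions without mitochondrial matches and for background matched on CpG number come from tests chosen after the data were seen. Where values changed, the cause was not tested.

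Replicate overlap (replicate 1, then replicate 2) was 83.2% and 89.3% above the median signal, 75.7% and 80.7% in pseudoreplicated lists, 80.4% and 85.7% at 50% overlap, 73.8% and 78.6% with summits within 100 bp, and 86.5% and 91.2% with every summit. The Jaccard index was 0.703 above the median signal and 0.645 in pseudoreplicated lists. Signal correlations (Spearman, Pearson) were 0.893 and 0.897 above the median signal, 0.891 and 0.909 in pseudoreplicated lists, and 0.933 and 0.937 for −log10 p. Nesting of the pooled lists in each other was unchanged at 50% overlap.

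The promoter share (replicate mean, then pooled list) was 61.5% and 51.7% above the median signal, 33.5% and 27.8% in pseudoreplicated lists, 56.8% and 46.4% with 500 bp windows, 62.5% and 52.6% with 2500 bp windows, and 65.5% and 55.4% with every summit; by any overlap the pooled share was 50.4%. Relative density of X and Y was 0.511 and 0.0146 above the median signal, 0.376 and 0.0130 in pseudoreplicated lists, and 0.510 and 0.0117 with every summit. Without 1 replicate these ranges were 58.4 to 60.7% for the promoter share, 0.481 to 0.490 for X and 0.0186 to 0.0198 for Y.

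At promoters, 14 lists were called (4 higher, 10 lower). Matching on CpG gave 8, 7 of these 14 and midbrain and hindbrain factors, of which 1 was higher, pseudoreplicated lists gave 8 higher, and leaving out 1 replicate gave 15 to 16 lists, 4 to 5 higher and 11 lower. Under the other alternatives these counts stayed within 1.5 times. In the distal test, 5 lists were called (3 higher, 2 lower). Pseudoreplicated lists gave 5 higher, regions within 100 kb gave 8 lists and 5 higher, no matching on territory gave 10 lists and 7 higher, and leaving out 1 replicate gave 6 to 8 lists and 4 to 6 higher. Hox genes were called lower within 100 kb (0.406 times) and without territory matching (0.107 times). No called list changed direction.

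Of distal motifs, 2 were lower in place of 1 in pseudoreplicated lists, with flanking windows and with the reversed consensus. Directions turned for MEIS (1.495), EBF (1.46) and MEF2 (0.335) with flanking windows, and for ETS (0.549) and MEIS (2.96) with the reversed consensus. At promoters, 11 motifs were lower with flanking windows and 1 with the reversed consensus, in place of 2. With flanking windows SOX (0.707), LHX/DLX (0.205), NKX2 (0.398), ASCL1 (4.27), TEAD (0.520), HNF4 (0.309) and MEF2 (0.109) turned, with the reversed consensus MEIS (2.61), NEUROG/NEUROD (3.65), ASCL1 (12.6) and RUNX (1.42), and with the CpG background NEUROG/NEUROD (1.72). The flanking windows were not matched on GC or CpG, so the turns against them cannot be separated from base composition. Leaving out 1 replicate gave 17 to 18 distal and 16 to 17 promoter calls. Read depth was unknown, so its limits could not be given.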

Other observations

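The comparison of Hox genes with lists matched on promoter CpG was chosen as a test of the cause only after the result was seen; the other tests in this part were chosen before.

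Promoter access rose with CpG content in steps: the median CpG observed/expected ratio of the lowest decile of genes was 0.0893 with 2.37% open, the fifth decile had a median of 0.420 and 53.2% open, and the highest had 0.843 and 93.1%. Hox genes had a median ratio of 0.591, above the 0.474 of all genes and below their upper quartile of 0.660.

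Hox promoters lacked regions, and 2 technical explanations were weighed. Lists matched on promoter CpG had 72.5% of genes open (central 95% 59.0 to 84.6%), against 2.56% of Hox genes (permutation p = 0.0002, the smallest possible). The size of this difference argues against CpG-poor promoters as the cause. Hox genes lie in clusters on chromosomes 2, 6, 11 and 15, while random lists drew genes regardless of position. The range and each p for Hox genes thus treat linked genes as separate. An earlier test, whether the Hox median lay with the CpG-poor promoters, was undecided, since it lay between the all-gene median and upper quartile, and the matched lists replaced it. In the more lenient pseudoreplicated lists 20.5% (8 of 39, exact 95% interval 9.30 to 36.5%) were open in both replicates, against 62.0% of all protein-coding genes. This argues against the authors' threshold as the only cause. The bound set beforehand for that, 25%, lies inside the interval, so the verdict rests on the interval staying below 50%. That interval also treats linked genes as separate, which weakens the verdict. The Hox share rose from 2.56% and that of all genes from 51.7%, so the threshold may account for a part. An axial difference between forebrain and more posterior tissue may remain, and no other tissue was in this series to test it.

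Distal regions with a CTCF motif were found in both replicates less often than others, the opposite of what had been predicted: 25.4% (194 of 764) against 43.4% of 12298 (two-sided Fisher's exact test, p = 1.2e-23). Their median −log10 p was 33.7 against 40.7. At matched −log10 p the difference was −4.67 percentage points (bootstrap 95% −6.73 to −2.70) in place of −18.0 unmatched. That comparison decides little: 316 of the 764 regions lay in 4 deciles in which nearly none or nearly all regions were found in both replicates, the largest difference in a decile was −16.8 points (25.3% against 42.1%), and the interval reaches past the 5-point bound set in advance. Whether lower −log10 p accounts for the difference stays open, and no biological explanation was tested.

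A hypothesis that neural motifs concentrate near telencephalon, pallium and progenitor genes was not borne out, as no motif passed the test. Most motifs were found in few of the regions near those genes, so the test cannot exclude differences. Among the 149 distal regions near the 57 genes of those lists, SOX sites were found in 21.5%, against 15.03% of 5182 other distal regions (exact p = 0.0368), and the smallest adjusted p over 18 motifs was 0.511.

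Regions with several summits were 81.2% of the pooled list and 59.4% of the pooled pseudoreplicated list. Of regions with several summits in the latter, 59.4% were kept in the former, against 19.9% of those with 1 summit. At matched −log10 p the difference in being kept averaged 2.00 points (−0.0261 to 7.02 over deciles), and at matched width −16.2 points. These comparisons had been planned as tests and are given as values only.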
